A study of Paralichthys olivaceus with 6 samples.

How the data were processed

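Libraries were made by the submitters from olive flounder hindbrain RNA with a stranded mRNA kit and sequenced as 100-bp paired ends, per the labels' protocols. The authors deposited 1 table of raw read counts per library, with whole numbers for 24395 genes and no rows for unassigned reads. The submitters' processing notes name Trimmomatic 0.30, TopHat2 2.0.11 and HTSeq 0.11.1. The genome build, the annotation, the strand setting and the counting mode are not given in the sources used here. How reads shared between duplicated genes, which are common in teleosts, or between overlapping genes were assigned is therefore not known, and values of close paralogs carry that uncertainty. Totals per library lay between 18081694 and 22805563 counts, and no library pair of a group differed by as little as sampling noise (chi-square per gene of at least 17.8 within groups).

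Libraries were grouped by title and source name, which give 3 bold and 3 shy libraries. The personality characteristic gives the opposite word for each of the 6, so the groups are called titled bold and titled shy and the direction of any difference depends on which label is right. No library was left out. The identifiers were 9665 gene symbols and 14730 LOC numbers. Of the LOC numbers, 11455 matched a gene number of the RefSeq annotation of assembly ASM2471397v2, which gave 5666 of them a symbol, and 9064 stayed without one. That annotation was used for names only.

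The following choices were made before the data were examined: the test, the groups, the gene lists, the rule for named genes and most of the other settings tried. Genes were kept by edgeR's filterByExpr, which left 19755, of which 13587 had a symbol. Counts were scaled by TMM and tested two-sided with edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest), and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 22.9%, and the median SE of a log2 fold was 0.199. CPM values use TMM-scaled library sizes, and DESeq2 results its own size factors. Of 42 gene lists, 41 had at least 5 tested members and were tested. The list of mitochondrially encoded genes matched no row of the count tables. Symbols were matched with or without a teleost duplicate suffix, and no gene descriptions were used. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, two-sided, with Benjamini-Hochberg adjustment over the 41 lists. Camera with an estimated correlation and fry were run beside it. Within a list, edgeR's p-values were also adjusted over the list alone.

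By the rule for named genes, since no gene was called, the 10 genes with the smallest unadjusted p are given as values. For lists described in detail, the 2 members with the smallest p are given. Some genes that the rule selects are not reported here. Unnamed loci are limited to 2 per direction. Genes named outside this rule are said to have been chosen after their values were seen, as are the abundant genes and the gene neurod2, and some lists are given by their median or adjusted p alone.

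The alternatives were RLE, upper-quartile and library-total scaling, DESeq2, limma-voom with and without library quality weights, no filter, a filter of 1 CPM in 3 libraries, estimation without robustness, a fold minimum of 1.2, leaving out each library, and a replicate block. A correction for GC content and gene length was planned and not run, because GC content was not used here and the build behind the counts is not given. Added after the data were seen were a fit without both libraries numbered 1, camera with an estimated correlation in the fits that left libraries out, and a list test without members that the suffix rule had matched to genes of another function. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, and for the plots Python 3.11.15 and matplotlib 3.10.9.

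The edgeR and camera steps were tested on simulated data for the comparison of titled bold with titled shy, with counts for 19755 genes in 5 sets, each with 200 changed genes. Of the genes changed 2-fold 47.8% were recovered and of those changed 4-fold 82.0%, with on average 14 false calls among 147. A list shifted 1.5-fold was called in 5 of 5 sets and no other list was. Changes of these sizes in single genes, and smaller ones, can therefore be missed with 3 libraries per group. Genes were drawn independently in the simulated sets, so the list result does not show how camera behaves where genes of a list move together. The recovery rates and false calls for single genes likewise hold only for independently drawn genes.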

Results

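The series compared hindbrain gene expression of olive flounder (Paralichthys olivaceus), a farmed flatfish, between fish selected as bold and fish selected as shy, and its title also names oxygen metabolism. RNA-seq read counts were analysed for 6 libraries, 3 per group. The title and the source name of each library give one personality and its personality characteristic gives the opposite one, for all 6 libraries. Both labels make the same 2 groups, so the libraries are named here as titled bold or titled shy, and every direction given below turns around if the characteristic is the correct label. Library totals lay between 18081694 and 22805563 counts over 24395 genes, so that 3 counts corresponded to between 0.132 and 0.174 CPM, counts scaled to the same total in every library. The labels speak of RNA from 6 individuals without saying whether each library pooled 6 fish or the series used 6 fish in all, and the p-values measure only the spread between these libraries. Values after ± are SDs over the 3 libraries of a group for CPM, over all 6 libraries where no group is named, and SEs for log2 folds.

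The most abundant named transcripts encoded secreted and neuronal proteins, led by epd, which encodes the extracellular glycoprotein ependymin, at 10510 ± 2101 CPM, the fetuin gene ahsg2 at 8769 ± 1260 CPM and the transferrin gene tfa at 5223 ± 1284 CPM. The synaptic gene snap25 followed at 4234 ± 735 CPM. The GABA-synthesis gene gad2 stood at 428 ± 49.6 CPM and the vesicular glutamate transporter gene slc17a6b at 146 ± 37.2 CPM. The GABA-A receptor subunit gene gabra6b, a marker of cerebellar granule cells in other vertebrates, reached 381 ± 30.6 CPM. Another vesicular glutamate transporter gene, slc17a7a, named after its values were seen, had 9 reads in all 6 libraries together. The share of granule cells was not estimated.

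Genes that mark position along the brain were unevenly represented. Hox genes, which pattern the hindbrain and spinal cord, had between 10 and 29 reads per library summed over 41 genes. Of these, 25 had no read in any library, none passed the filter for testing, and the highest mean was 0.336 ± 0.0658 CPM, for hoxa2. The hindbrain and spinal cord list held 16 members of other families, of which 7 had a mean of at least 1 CPM and 5 of at least 10 CPM. Those 5 were lmx1al at 46.9 ± 19.5 CPM, gata3 at 26.2 ± 4.47 CPM, isl1 at 26.0 ± 4.78 CPM, lmx1b at 21.8 ± 8.45 CPM and mafba at 21.1 ± 2.93 CPM, while phox2a had no read. The serotonergic neuron genes tph2 and fev had 0.812 ± 0.586 and 0.200 ± 0.182 CPM, and the noradrenergic gene dbh had 11.4 ± 3.16 CPM. Of 31 forebrain and midbrain genes, 15 had a mean of at least 1 CPM and 7 of at least 10 CPM. In these libraries, the hypothalamic patterning genes nkx2-1 and nkx2.4b had 29.4 ± 3.81 and 35.9 ± 6.64 CPM, six3 had 46.0 ± 6.80 CPM, and dlx1 and gsx1 had 35.6 ± 7.10 and 73.8 ± 23 CPM. The forebrain genes emx2, fezf2 and six6 were lower, at 1.63 ± 1.33, 1.62 ± 1.49 and 3.28 ± 2.78 CPM. The midbrain-hindbrain boundary gene en2 averaged 5.11 ± 0.995 CPM. The individual genes in these sentences were chosen after their values were seen.

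**Figure D1:**
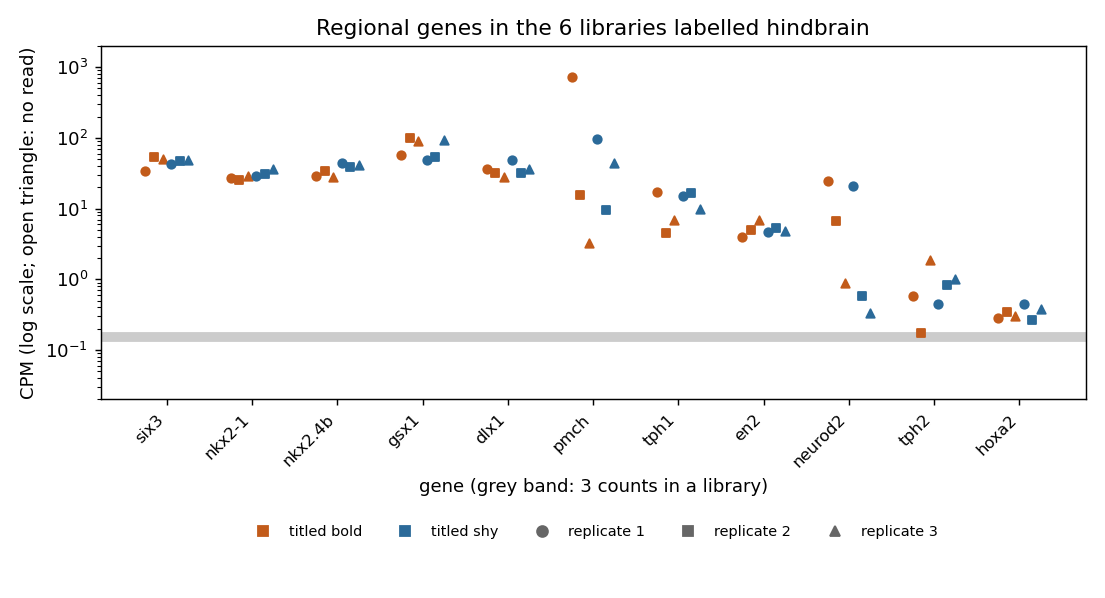
CPM of 11 regional genes (y axis, log scale) in each of the 6 libraries. Colours give the group by title and symbols the replicate number, the grey band marks 3 counts in a library and an open triangle stands for no read. The genes six3 and nkx2-1 lie above 20 CPM in all libraries, whereas hoxa2 stays at or below 0.44 CPM.

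Between libraries titled bold and libraries titled shy, the gene with the smallest p was the unnamed locus LOC109625972, at 66.3 ± 11.5 against 29.4 ± 3.84 CPM, a log2 fold of 1.17 ± 0.16. The ERK phosphatase gene dusp5 had 46.4 ± 5.62 CPM in libraries titled bold and 27.1 ± 0.689 CPM in libraries titled shy, a log2 fold of 0.78 ± 0.12. The constitutively active receptor gene gpr3 (LOC109631659 in the files), which raises cAMP, had 18.6 ± 2.31 against 10.1 ± 0.326 CPM, a log2 fold of 0.88 ± 0.16. The chemokine-scavenging receptor gene ackr3 had 32.2 ± 2.51 against 49.2 ± 1.97 CPM, a log2 fold of -0.61 ± 0.11. None of these 4 differences passed edgeR's test across all genes, while DESeq2 called all 4.

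With edgeR's quasi-likelihood test, 0 of 19755 tested genes were called at a Benjamini-Hochberg adjusted p under 0.05. The smallest adjusted p was 0.943, and 690 genes had an unadjusted p under 0.05, where chance alone gives 988. Of the 690, 344 were higher and 346 lower in libraries titled bold. The count at an unadjusted p under 0.05 depended on the libraries used. It was 2372 without titled bold 1, with a smallest edgeR adjusted p of 0.121, and between 516 and 611 without any other 1 library. With the replicate block it was 1160, and without both libraries numbered 1 it was 1339, with a smallest adjusted p of 0.0743. A split that mixes the groups, titled bold 1, titled shy 1 and titled shy 3 against the rest, gave 2347 in edgeR, with 0 genes called. A count of that size is therefore not particular to the groups by title. limma-voom called 0 genes, with 718 at an unadjusted p under 0.05, and limma-voom with library quality weights called 0, with 1851. DESeq2 called 13 genes, 10 higher and 3 lower in libraries titled bold, with 810 at an unadjusted p under 0.05. The 2 groups did not overlap in 1882 tested genes, or 9.53%, where chance gives 10%.

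Of the 10 genes with the smallest unadjusted p, 9 are described here, all with groups that did not overlap and edgeR adjusted p-values between 0.943 and 0.955. Besides LOC109625972, dusp5, gpr3 and ackr3 they included rtn4rl2a (LOC109627275 in the files), a Nogo receptor family gene, at 60.7 ± 9.46 against 26.1 ± 8.07 CPM and a log2 fold of 1.22 ± 0.22. The adhesion receptor gene adgrg7 had 3.91 ± 0.576 against 0.945 ± 0.478 CPM, with a log2 fold of 2.05 ± 0.42. The gene pde4dip (LOC109646245 in the files), which encodes a Golgi and centrosome scaffold of phosphodiesterase 4D, had 61.8 ± 5.34 against 92.8 ± 9.37 CPM, with a log2 fold of -0.59 ± 0.12. Among the other unnamed loci, LOC109628858 had a log2 fold of 1.41 ± 0.28 and LOC109647828 of -0.69 ± 0.14. DESeq2 called 8 of these 9 genes, all but LOC109647828. Its adjusted p was 5.33e-07 for LOC109625972, 0.00152 for dusp5 and rtn4rl2a, 0.00691 for gpr3, 0.0189 for ackr3 and adgrg7, and 0.0498 for pde4dip.

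**Figure D2:**
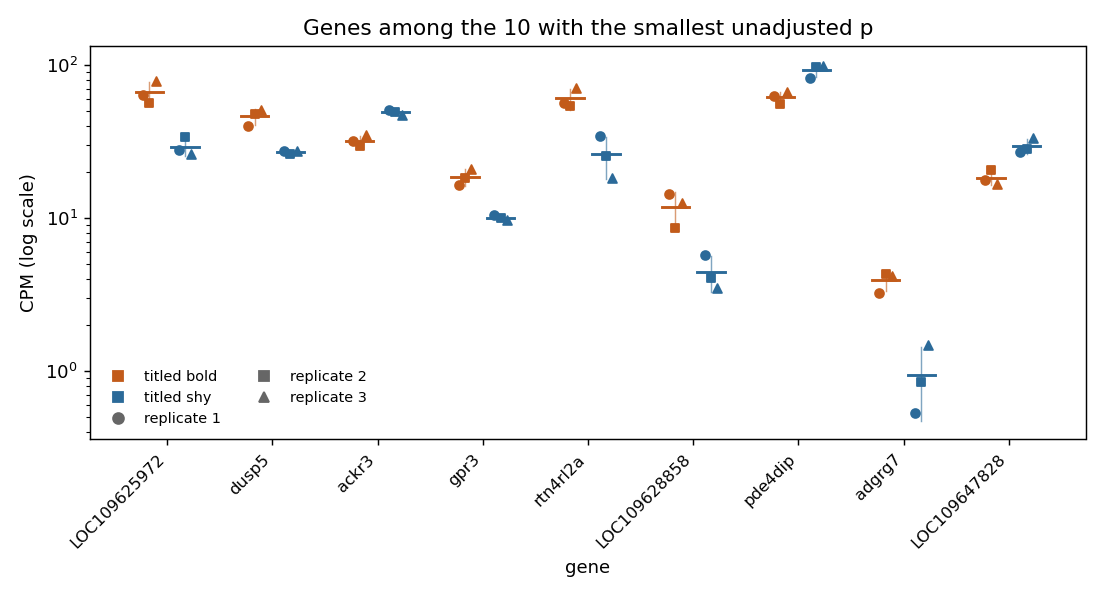
CPM per library (y axis, log scale) of 9 of the 10 genes with the smallest unadjusted p in edgeR. Points are libraries, horizontal lines group means and vertical lines 1 SD, and the groups do not overlap in any of the 9 genes.

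Immediate early genes, which neurons transcribe soon after activity, were the gene list with the smallest camera p, and most of its members were estimated higher in libraries titled bold. The median log2 fold of its 28 tested members was 0.27, with 21 members above 0 and 7 below. The AP-1 gene fosb had 6.15 ± 1.26 CPM in libraries titled bold and 2.04 ± 1.02 CPM in libraries titled shy, a log2 fold of 1.59 ± 0.40. The neurotrophin gene bdnf had 40.8 ± 8.10 against 26.9 ± 1.80 CPM, a log2 fold of 0.60 ± 0.16. The other members with an unadjusted p under 0.05, named after their values were seen, were jund at a log2 fold of 0.58 ± 0.15, junb at 0.61 ± 0.19 and egr1 at 0.39 ± 0.14. The list was called by camera with its preset correlation (adjusted p = 0.0010), and adjusted p = 0.917 with an estimated correlation. Over all genes 0 members were called, and adjusted over the list alone 3 were, fosb, bdnf and jund, each with an edgeR adjusted p of 0.0452. With the preset correlation the list stayed called without any 1 of the 6 libraries, and without titled bold 2 its median log2 fold was 0.10 and its mean 0.26, against a mean of 0.25 with all libraries, with adjusted p = 0.952 with an estimated correlation in that fit.

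**Figure D3:**
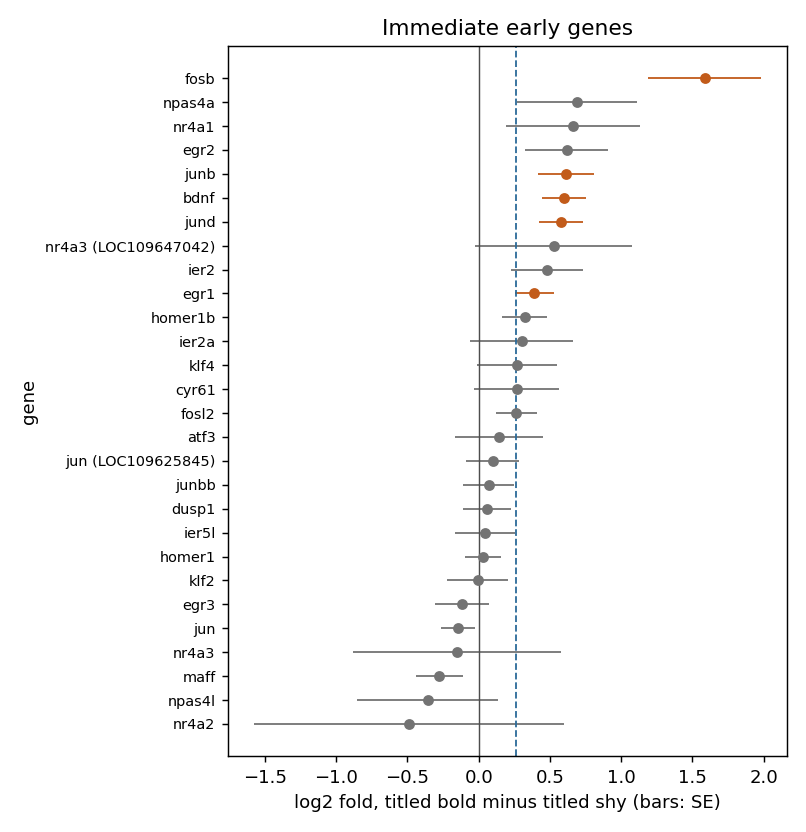
Log2 fold of each tested immediate early gene, titled bold minus titled shy (x axis), with its SE as a bar. Orange points have an unadjusted p under 0.05 and the dashed line is the list's median, 0.27. The highest value is that of fosb, 1.59.

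Of 41 lists tested, camera with its preset correlation called 5, all higher in libraries titled bold, and with an estimated correlation it called 0. Averaged over members, the libraries of the 2 groups overlapped in each called list except the immediate early genes. For cholesterol and fatty acid synthesis the highest library was titled shy 2. With an estimated correlation the 5 lists shared an adjusted p of 0.917, a tie made by the Benjamini-Hochberg adjustment. Their unadjusted camera p-values were 0.0615 for immediate early genes, 0.0750 for cerebellar granule cells and 0.285 for cholesterol and fatty acid synthesis. They were 0.306 for meninges, fibroblasts and choroid plexus and 0.568 for oxidative phosphorylation. The preset test called 3 lists without titled bold 1, 2 higher and 1 lower, and 9 without titled shy 2, 8 higher and 1 lower. The rotation test fry called 0 lists for movement in one direction and 0 for movement in either direction, with lowest adjusted p-values of 0.802 and 0.579.

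Genes of the meninges, fibroblasts and choroid plexus had a median log2 fold of 0.19 over 25 members, 18 of them above 0. The collagen gene col1a1a had 55.1 ± 13.8 CPM in libraries titled bold and 32.9 ± 11.7 CPM in libraries titled shy, and igfbp2a, which encodes a binding protein of insulin-like growth factors, 12.6 ± 1.46 against 9.59 ± 1.13 CPM. This list had a camera adjusted p = 0.0233, and adjusted p = 0.917 with an estimated correlation. Over all genes 0 members were called, 1 had an unadjusted p under 0.05, and adjusted over the list alone 0 were called by edgeR. Camera's adjusted p was 0.372 without titled bold 1, 0.102 without titled shy 1 and 0.339 without titled shy 3, and the median was 0.01, 0.11 and 0.12 in these fits and 0.41 without titled shy 2.

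Genes of cholesterol and fatty acid synthesis had a median log2 fold of 0.12 over 36 members, 27 of them above 0. The mevalonate pathway gene pmvk had 39.4 ± 4.32 against 29.9 ± 1.93 CPM. The list had a camera adjusted p = 0.0289, and adjusted p = 0.917 with an estimated correlation. Over all genes 0 members were called, 3 had an unadjusted p under 0.05, of which 2 were higher and 1 lower in libraries titled bold, and adjusted over the list alone 0 were called by edgeR. Camera's adjusted p was 0.194 without titled bold 1 and 0.767 without titled shy 1, and the list's median was 0.01 without titled shy 1, 0.23 without titled shy 2 and 0.20 without titled shy 3.

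Cerebellar granule cell genes had a median log2 fold of 0.17 over 18 members, 14 of them above 0. The zinc-finger genes zic2, at 77.0 ± 8.54 against 61.5 ± 14.4 CPM, and zic5, at 15.3 ± 2.84 against 12.0 ± 1.58 CPM, had the smallest p-values. The list had a camera adjusted p = 0.0443, and adjusted p = 0.917 with an estimated correlation. Both over all genes and adjusted over the list alone 0 members were called by edgeR, and 0 had an unadjusted p under 0.05. Camera's adjusted p was 0.270 without titled bold 1, 0.117 without titled bold 2 and 0.339 without titled shy 3, and the median was 0.28 without titled bold 3.

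Nuclear genes of oxidative phosphorylation had a median log2 fold of 0.07 over 82 members, 63 of them above 0. The complex I gene ndufb2 had 67.1 ± 2.73 against 55.9 ± 3.39 CPM, and atp5i, which encodes a subunit of ATP synthase, 28.6 ± 2.27 against 37.5 ± 8.58 CPM. The list had a camera adjusted p = 0.0443, and adjusted p = 0.917 with an estimated correlation. Over all genes 0 members were called, 1 had an unadjusted p under 0.05, and adjusted over the list alone 0 were called by edgeR. Camera's adjusted p was 0.369 without titled bold 2, 0.598 without titled bold 3, 0.984 without titled shy 1 and 0.102 when libraries were scaled by their totals only. The median was between 0.02 and 0.03 in the first 3 of these fits, 0.04 with library totals, 0.14 without titled bold 1 and 0.13 without titled shy 3.

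**Figure D4:**
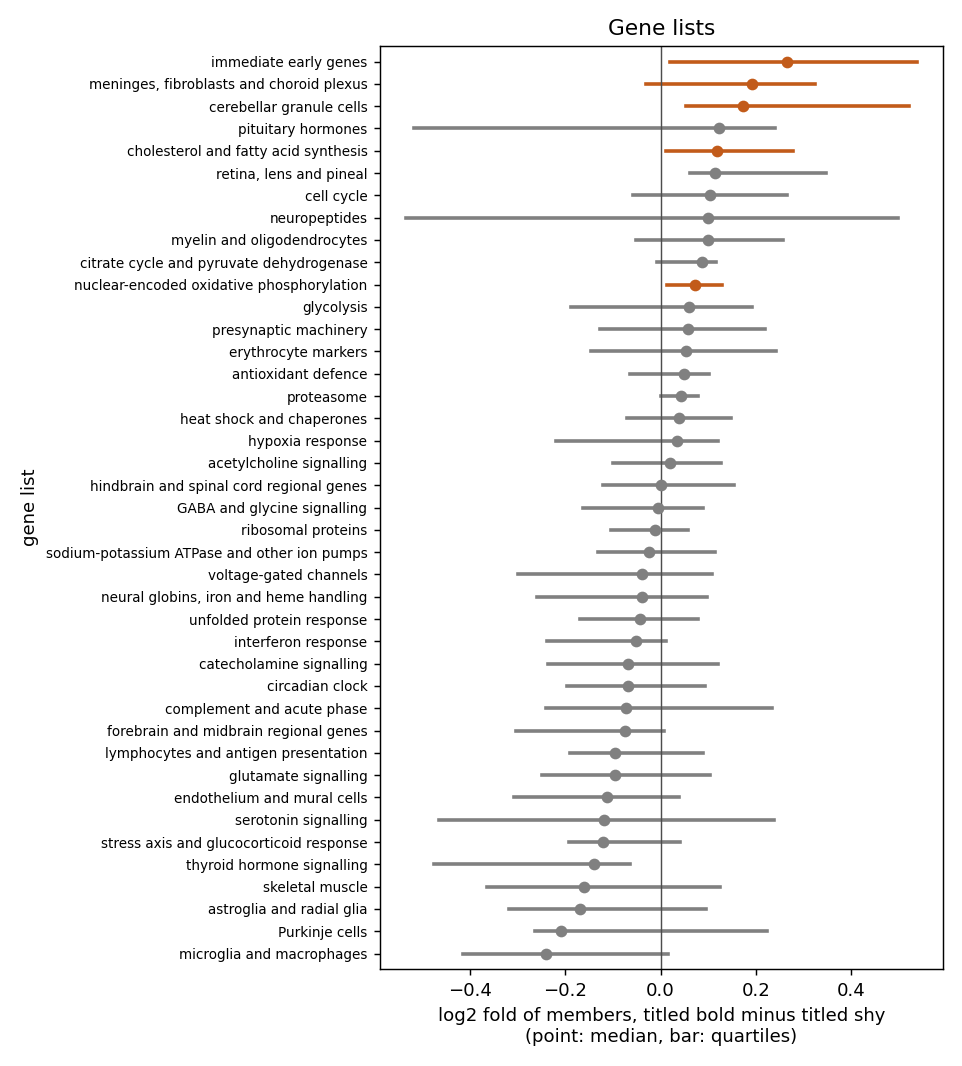
Median log2 fold (points) and quartiles (bars) of the tested members of each of the 41 gene lists, titled bold minus titled shy (x axis). Orange marks the 5 lists called by camera with its preset correlation, whose medians lie between 0.07 and 0.27.

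The other lists on oxygen supply and energy metabolism were not called by camera. Erythrocyte markers had a median log2 fold of 0.05 and an adjusted p of 0.671, and their members with the smallest p were gata1b, at 0.40 ± 0.0989 against 0.659 ± 0.0788 CPM, and the anion exchanger gene slc4a1a, at 3.78 ± 1.46 against 2.63 ± 0.764 CPM. Neural globins, iron and heme handling had a median of -0.04 and an adjusted p of 0.852, with the heme oxygenase gene hmox1a at 3.70 ± 2.79 against 1.56 ± 1.02 CPM and tfa at 4592 ± 1071 against 5853 ± 1336 CPM. Hypoxia response genes had a median of 0.03 and an adjusted p of 0.762, with the lysyl oxidase gene loxa at 5.17 ± 0.836 against 9.18 ± 1.61 CPM and epas1a, which encodes a hypoxia-inducible factor, at 3.47 ± 1.59 against 1.42 ± 0.257 CPM. Its paralog epas1, named after its values were seen, went the other way, at 5.57 ± 4.75 against 8.41 ± 3.42 CPM. Glycolysis had a median of 0.06 and an adjusted p of 0.479. Its gene aldoc had 2101 ± 27.2 against 1723 ± 47.6 CPM, and the locus named gapdh had 5.59 ± 1.89 against 22.4 ± 13.9 CPM, which DESeq2 called with an adjusted p of 0.0349. Genes of the citrate cycle and pyruvate dehydrogenase had a median of 0.09 and an adjusted p of 0.349, with the citrate synthase gene cs at 430 ± 47.2 against 354 ± 6.69 CPM and pdhb at 42.9 ± 7.73 against 51.6 ± 5.52 CPM. Antioxidant defence had a median of 0.05 and an adjusted p of 0.351.

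Transmitter and peptide lists were not called by camera either. Serotonin signalling had a median log2 fold of -0.12 and a camera adjusted p of 0.979, with 9 members above 0 and 11 below. Its transporter gene slc6a4 had 9.36 ± 0.477 CPM in libraries titled bold and 5.91 ± 0.260 CPM in libraries titled shy, a log2 fold of 0.66 ± 0.19. The receptor gene htr7c had 10.4 ± 1.6 against 6.91 ± 1.01 CPM. The transporter paralog slc6a4b, named after its values were seen, went the other way, at 1.64 ± 1.90 against 3.94 ± 3.71 CPM. Catecholamine signalling had a median of -0.07 and a camera adjusted p of 0.943, with 8 members above 0 and 11 below. Its dopamine receptor gene drd3 had 7.97 ± 0.880 against 5.50 ± 1.01 CPM and the noradrenaline-synthesis gene dbh 13.6 ± 1.93 against 9.22 ± 2.68 CPM. Among neuropeptides, with an adjusted p of 0.564, the cholecystokinin gene cckb had 227 ± 47.9 against 159 ± 6.99 CPM, a log2 fold of 0.51 ± 0.15, and cart3 had 10.8 ± 4.6 against 5.63 ± 0.332 CPM. In the stress axis and glucocorticoid response, with an adjusted p of 0.564, the urotensin gene uts1 had 3.20 ± 3.23 against 0.955 ± 0.357 CPM and the glucocorticoid receptor gene nr3c1 14.4 ± 3.65 against 19.3 ± 1.29 CPM. Thyroid hormone signalling had a median log2 fold of -0.14 and the smallest adjusted p of the lists not called, 0.0666, and its genes crym and trhrb, for a thyroid hormone binding protein and a thyrotropin-releasing hormone receptor, had 19.0 ± 4.30 against 27.9 ± 4.10 CPM and 8.24 ± 1.67 against 12.3 ± 1.13 CPM. This list was called lower without titled bold 1 (median -0.49, camera adjusted p = 0.0267, and adjusted p = 0.894 with an estimated correlation) and without titled shy 2 (adjusted p = 0.0139, and adjusted p = 0.813 with an estimated correlation), and its median was -0.07 without titled bold 2. The camera adjusted p was 0.857 for GABA and glycine signalling, 0.762 for glutamate signalling and 0.762 for acetylcholine signalling, with medians of -0.01, -0.10 and 0.02. The glutamate median was -0.226 without titled bold 1 and 0.015 without titled bold 2. Presynaptic machinery had a median of 0.06 and an adjusted p of 0.351, voltage-gated channels -0.04 and 0.349, and sodium-potassium ATPase and other ion pumps -0.03 and 0.966.

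Markers of other cell types and tissues gave no further camera call. Microglia and macrophages had a median log2 fold of -0.24 and an adjusted p of 0.268, with the transcription factor gene spi1 at 2.42 ± 0.358 against 4.89 ± 2.66 CPM and cxcr4 at 2.65 ± 0.885 against 4.53 ± 0.487 CPM. The median of this list was -0.15 without titled bold 2 and 0.08 without titled shy 2, and the list was called lower without titled shy 3 (median -0.32, camera adjusted p = 0.000412, and adjusted p = 0.910 with an estimated correlation). Endothelium and mural cells had a median of -0.11 and an adjusted p of 0.182, with notch3 at 12.3 ± 6.79 against 24.5 ± 5.20 CPM and the tight junction gene cldn5 at 80.8 ± 1.94 against 95.4 ± 6.76 CPM. The median of this list was -0.01 without titled bold 3 (camera adjusted p = 0.603) and -0.06 without titled shy 2. It was called lower without titled bold 2 (median -0.21, camera adjusted p = 0.00659, and adjusted p = 0.952 with an estimated correlation) and without titled shy 3 (median -0.13, adjusted p = 0.0331, and adjusted p = 0.910 with an estimated correlation). Myelin and oligodendrocytes had a median of 0.10 and astroglia and radial glia of -0.17, both with an adjusted p of 0.268. The myelin median was 0.18 without titled bold 1 and -0.02 without titled bold 2. Lymphocytes and antigen presentation had an adjusted p of 0.925, interferon response 0.979 and complement and acute phase 0.762. Pituitary hormones had an adjusted p of 0.853, with the somatolactin gene smtla at 1.10 ± 1.10 against 11.7 ± 14.7 CPM, and skeletal muscle had 0.762. Purkinje cells had a median of -0.21, which was 0.03 without titled bold 2, and an adjusted p of 0.853. The adjusted p was 0.445 for forebrain and midbrain regional genes, 0.671 for hindbrain and spinal cord regional genes and 0.268 for retina, lens and pineal.

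Among lists of general cell functions, camera's adjusted p was 0.231 for cell cycle, 0.349 for proteasome, 0.479 for heat shock and chaperones, 0.762 for the unfolded protein response, 0.762 for the circadian clock and 0.852 for ribosomal proteins. The ribosomal protein genes rpl38, at 167 ± 24.4 against 289 ± 64.0 CPM, and rps21, at 178 ± 27.5 against 290 ± 60.4 CPM, had the smallest p-values of their list, whose median was -0.01. In each of the 36 lists that were not called, 0 members were called by edgeR over all genes and 0 when adjusted over the list alone. In 10 of these lists the median or the mean differed in sign from the direction given by camera, namely hypoxia response, glycolysis, serotonin, catecholamine, stress axis, interferon, complement, pituitary, skeletal muscle and ion pumps. Without 1 library, camera with its preset correlation called 8 of the 36 lists and the median of 24 changed sign. Besides thyroid hormone signalling, microglia and endothelium, the lists so called were astroglia and ribosomal proteins (adjusted p = 0.00172) without titled shy 1, both lower, and erythrocyte markers (adjusted p = 0.0328), lymphocytes (0.0328) and retina, lens and pineal (0.0468) without titled shy 2, all higher. Over the 6 fits without 1 library the median of astroglia lay between -0.22, without titled shy 1, and -0.07, without titled shy 2, with -0.08 without titled shy 3. The range was -0.10 to 0.06 for ribosomal proteins, -0.01 to 0.13 for erythrocyte markers, -0.22 to 0.22 for lymphocytes and 0.10 to 0.21 for retina, lens and pineal. With an estimated correlation 0 lists were called in these fits, with a lowest adjusted p = 0.707. With other scalings the median of 4 lists changed sign or reached 0, namely hypoxia response, GABA and glycine, acetylcholine, and hindbrain and spinal cord regional genes.

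The libraries did not separate by group on the first principal components of log2 CPM. PC1 held 43.5% of the variance and set titled bold 2, at 72.3, apart from the other libraries, which lay between -34.3 and 13.3. Titled bold 1 and titled shy 1 lay together, at -34.2 and -34.3 on PC1 and 23.5 and 19.5 on PC2, which held 16.9%. Both held more of the transcription factor gene neurod2, at 24.8 and 20.9 CPM, than the other libraries, in which it lay between 0.332 and 6.78 CPM. Without both libraries numbered 1, an exclusion chosen after the data were seen, edgeR called 0 genes, and camera called 1 list, the immediate early genes, with an adjusted p of 0.00428, and adjusted p = 0.938 with an estimated correlation.

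**Figure D5:**
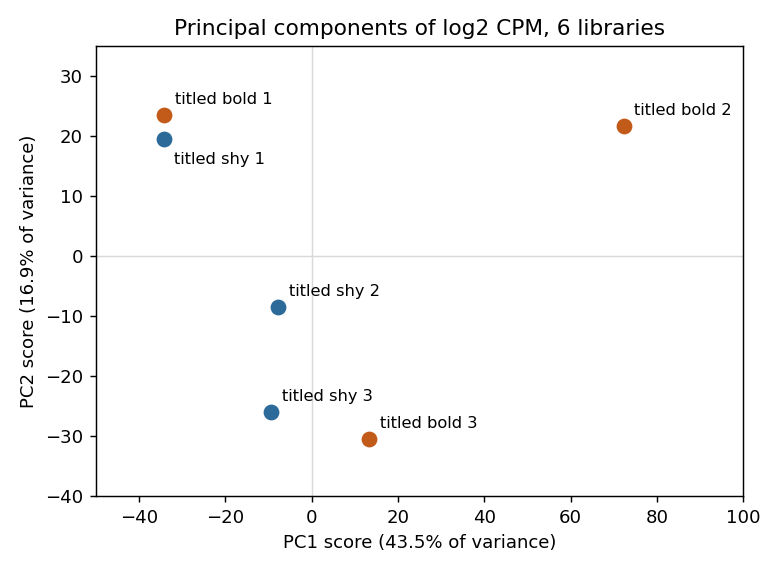
Scores of the 6 libraries on the first principal components of log2 CPM (x axis PC1, y axis PC2). Titled bold 2 lies at 72.3 on PC1, and titled bold 1 and titled shy 1 lie next to each other at -34.2 and -34.3.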

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

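The fit without both libraries numbered 1, the list test without mismatched members and the estimated correlation in fits that left libraries out were chosen after the data were seen; the other alternatives were planned. edgeR called 0 genes under RLE, upper-quartile and library-total scaling, with no filter, with a filter of 1 CPM in 3 libraries, without robust estimation, with a fold minimum of 1.2, without each library in turn (0 to 0) and without both libraries numbered 1. limma-voom called 0 with and without quality weights. DESeq2 called 13, and the cause of that difference was not tested. Each of the 9 genes named by their p kept its direction in its 18 alternative fits. They were chosen by smallest p in the same counts and their groups did not overlap, so this outcome was largely set beforehand. Of the 9 genes, 8 passed the threshold only with DESeq2. For dusp5 the log2 fold lay between 0.70 and 0.90 and the adjusted p between 0.00152 and 1. The 5 called lists were 0 with an estimated correlation, which allows for genes moving together, both with all libraries and over the 7 fits that left libraries out, and 0 with fry, which does not compare a list with other genes. Without 1 library the count of called lists lay between 3, without titled bold 1, and 9, without titled shy 2, and without both libraries numbered 1 it was 1; the cause was not tested. It was 5 without mismatched members, 5 with RLE scaling and 4 with library totals. Over the alternative fits of these 5 lists, counted once per list and fit, 44 kept the call and 26 lost it. Among the 36 other lists, 8 gained a call without 1 library, in 10 combinations of list and fit. Their remaining alternatives were not tallied. With the replicate block edgeR called 0 genes and camera with its preset correlation 6 lists, 5 higher and 1 lower in libraries titled bold. The 5 higher were those of the main fit, and which other list was lower was not recorded. An estimated correlation was not tried with the block. The numbers were not taken as pairs, because deviations of same-numbered libraries correlated at 0.32, 0.14 and 0.08; 5 of 6 libraries correlated best with their own number, a hint from the data and not from the design. The corrections for GC content and length, alone and with the block, were not run. Depth limits genes near 3 counts, between 0.132 and 0.174 CPM.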

Other observations

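The tests of how many genes are called over other splits, of presynaptic genes, of the mean of the immediate early genes without 1 library and of all Hox explanations were chosen after the results they bear on were seen; the splits for the lists and the immediate early genes and the median without 1 library were set before. Peptide genes of the hypothalamus varied widely between libraries of both groups. The melanin-concentrating hormone genes pmch and pmchl ranged from 3.30 to 724 CPM and from 14.6 to 1351 CPM over the 6 libraries. Corticotropin-releasing hormone, crh, ranged from 1.22 to 13.2 CPM, galanin, gal, from 1.97 to 20.8 CPM and the dopamine-synthesis gene th from 1.04 to 11.3 CPM. For each of these 5 genes the highest value of a group lay in its library numbered 1. These genes were picked after their values were seen. The spread between libraries of a group was therefore computed for all 41 lists. The median biological coefficient of variation of neuropeptides was 38.4%, where 10000 random lists matched on expression had a median of 24.3%, and that of pituitary hormones was 64.1% against 31.3%. Presynaptic machinery, at 15.6% against 13%, also lay above its random lists, while forebrain and midbrain regional genes, at 28.6% against 27.3%, lay at a percentile of 68.3. In all, 17 of the 41 lists lay at a percentile of 95 or above and 2, glycolysis and the proteasome, at 5 or below.

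The tryptophan hydroxylase gene tph1 had 11.7 ± 5.40 CPM (SD over 6 libraries), against 0.812 ± 0.586 CPM for tph2. The choline acetyltransferase gene chat had 1 read in all 6 libraries together, and the glycine transporter gene slc6a5 had 26. Neuroglobin, ngb, stood at 27.5 ± 4.45 CPM, globin X, xgb, at 2.32 ± 0.525 CPM, and the myoglobin gene mb had 5 reads in all.

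Libraries labelled hindbrain held almost no Hox reads. Cerebellum alone, a part of the hindbrain that develops without Hox expression, would leave forebrain and midbrain genes low, yet 5 of that list's 31 members had at least 10 CPM in each library. Whether reads of Hox genes were lost in counting stays open, because the 16 hindbrain and spinal cord genes of other families had a median of 0.48 CPM but went both ways, with 9 below 1 CPM and 5 at 10 CPM or more. Tissue rostral to the hindbrain may make up most of each library, and this stays open too. Of 31 forebrain and midbrain genes, 7 (22.6%) had a mean of at least 10 CPM and 16 lay below 1 CPM. Of the hindbrain and spinal cord genes of other families, 31.2% had a mean of at least 10 CPM. These shares cannot decide the question, because genes of either list may also be expressed in other regions. The share of each region was not estimated, and no biological explanation was tested, since both groups show the pattern.

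Of the 28 immediate early genes 21 were higher in libraries titled bold, and camera called the list with its preset correlation but not with an estimated one (adjusted p = 0.917 with an estimated correlation). Whether 1 library carries the difference stays open: without titled bold 2 the list's median log2 fold was 0.10 in place of 0.27 but its mean 0.26 in place of 0.25, and camera with its preset correlation still called the list (adjusted p = 0.00111, and adjusted p = 0.952 with an estimated correlation), while over all 6 fits without 1 library the mean lay between 0.22 and 0.30. Averaged over members, deviations of log2 CPM from each gene's mean were 0.105, 0.059 and 0.197 in libraries titled bold 1 to 3. In libraries titled shy 1 to 3 they were -0.071, -0.015 and -0.275. The mean therefore did not rest on 1 library, while the median leaves this open. A larger share of neurons in libraries titled bold would lift presynaptic genes alike. Their median was 0.06 against the immediate early median of 0.27, and lower in every fit without 1 library, with 0.06 against 0.10 without titled bold 2. Medians of glutamate, GABA and glycine, and acetylcholine signalling were -0.10, -0.01 and 0.02, and that of voltage-gated channels was -0.04. The presynaptic upper quartile was 0.22 with all libraries, but above the immediate early median in 4 of the 6 fits without 1 library. With such a spread and 3 libraries per group, a larger share of neurons and a change in the immediate early genes alone cannot be told apart. The 6 libraries make only 10 splits into 3 and 3, too few for a share under 0.05. The camera p of this list was 2.44e-05 in the real split and at smallest 0.00124 in the others, so that 1 of the 10 splits, the real one, had a p as small. A difference between personalities and a difference in handling before death both stay open as untested.

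For the counts of calls the 10 splits are again too few for a share under 0.05. The real split called 0 genes and the highest of the others 3. All 10 splits had as many as the real one, which a count of 0 fixes in advance, so this comparison decides nothing. The real split called 5 lists and the highest of the others 14, the split of titled bold 1, titled shy 1 and titled shy 3 from the rest, and 7 of the 10 splits, the real one included, had as many.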
